A study of Mus musculus with 34 samples.

How the data were processed

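Chromatin immunoprecipitation with an antibody against the FLAG tag, followed by sequencing, was done on mouse tissue of embryonic day 11.5 and on embryonic stem cells (ESC). The tagged proteins were SMARCA4, the ATPase of the SWI/SNF (BAF) chromatin remodelling complex, SMARCC2, a further subunit of that complex, the histone acetyltransferase EP300, and the nuclear receptor coactivators NCOA1 and NCOA2. Histone marks were measured in limb and forebrain of CD1 embryos. Per the labels, tissue was pooled from about 150 or 300 embryos, chromatin fragments of 300 to 500 bp were sequenced, and reads were 36 or 50 bp long. The series has 34 samples. Peak lists of 30 of them were used: 14 FLAG lists (8 of SMARCA4), 6 controls of FLAG samples that the labels call input controls, 7 histone mark lists and 3 histone inputs. The control samples of SMARCA4 in heart, forebrain, limb and neural tube were not analysed here.

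Reads were mapped with BWA to mm9, per the submitters' processing notes, which name no version. The peak caller was not given in the sources used here, and each list belongs to 1 library. Per the file headers, 16 lists are tables that give each peak's position, summit, the count of tags in it, a score from the log10 of p, a fold enrichment ratio, a false discovery rate in percent, a conservation score, and the nearest gene with its distance. These values are the authors' and were used only to describe, rank or filter peaks within a list. Every such score in the deposited tables was at least 50. The authors' false discovery rate in percent was missing in every line of SMARCA4 ESC, SMARCA4 hindbrain, EP300 ESC and the 6 controls. Where given, its median was 100% in SMARCA4 midbrain, 56.4% in EP300 face, 18.2% in NCOA1 and 1.8% in NCOA2, and under 1% in SMARCA4 heart and both SMARCC2 lists. The other 14 deposited lists (SMARCA4 face, forebrain, neural tube and limb, and all histone lists and inputs) hold positions and a rank. All boundaries of the forebrain, neural tube and limb SMARCA4 lists fall on multiples of 50 bp, which was not so in the other lists. Only the tag count per peak shows depth, so library depth is unknown.

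Several labels were unclear. The tissue tag of the SMARCA4 hindbrain sample says forebrain, and the sample was kept as hindbrain after its title. The genotype tag names a SMARCA4 knock-in on samples of the other tagged proteins too. The SMARCA4 ESC description speaks of pooled embryos, and the histone protocol names heart and hindbrain although the samples are limb and forebrain. Whether an input control is unenriched chromatin of the tagged tissue or something else is not stated.

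Lists were compared by the share of peaks that overlapped another list by at least 1 bp. Each share has an exact 95% binomial (Clopper-Pearson) interval. Beside it stands the mean share over 100 circular shifts of the other list along each chromosome (chance). A ratio to that mean has a lower ceiling where the mean is larger, so such ratios alone do not rank pairs of lists. There was 1 library per condition and therefore no replicate check, so no p-value was computed and every comparison is of these libraries. Intervals cover counting error only. Pairs of lists were compared for all peaks and for peaks away from H3K4me3, a mark of active gene starts, of limb or forebrain. SMARCA4 lists were also merged into regions, which were counted by the number of tissues that held them.

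The tables give gene names without gene coordinates. The point from which the authors measured distances was worked out from summit and distance wherever at least 2 peaks agreed. This placed 18934 of 23432 gene names with 0 conflicts, and 67.3% of the points lay inside limb H3K4me3 regions, against 1.67% after shifts. When each table was held out in turn, the points gave the authors' gene to 81.2% to 96.9% of its peaks, with a median of 92.4%. A peak within 1 kb of such a point was called near a gene start. Names and synonyms were matched by chromosome to a RefSeq gene table of assembly GRCm38.p6, of which no coordinate was used. It matched 13017 of 16001 symbols with a point.

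Gene lists were fixed for face, forebrain, midbrain, hindbrain, neural tube, limb, heart and ESC, for erythroid cells and endothelium as other cell types, for housekeeping genes, and for SWI/SNF subunits with the tagged factors. The territory of a gene reached 100 kb to each side of its point. The mean number of peaks per gene was divided by the mean of 10000 random lists of the same size, matched in 10 bins of the total number of FLAG peaks in the territory. It is also given as a percentile among those lists. Values from 97.5 up or from 2.5 down were called. Random lists describe these libraries and give no p-value. Territories of neighbouring genes overlap, so peaks in a Hox cluster count for several members, which random lists do not copy. Genes without an exact point entered at the summit of their closest peak if it lay within 10 kb. That step was added after seeing the data, because under 80% of the ESC, limb and erythroid genes had a point without it. With it 14173 protein-coding genes were used, and the erythroid list still had only 7 of 12 genes.

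The named genes followed a rule. For each SMARCA4 list it took the 3 members of the tissue's own list with the most peaks, and the gene nearest to each of the 3 top peaks found in that tissue alone. For each of the other factors it took the 3 top peaks, for each mark in limb and forebrain the 3 top regions of that tissue alone, and for SMARCA4 peaks with H3K27me3 the 5 top peaks. Genes outside this rule were chosen after their values were seen. A gene that the rule named is not reported here. The gene lists, this rule, the comparisons and most alternatives were fixed before the data were examined. The alternatives were another overlap, midpoints within 500 bp, equal list lengths, the higher-scoring part of a list, peaks of control lists or of H3K4me3 left out, other territories, and each tissue left out. Added after seeing the data were a limit on the authors' false discovery rate, the use of exact gene points alone, and the omission of midbrain and hindbrain together.

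The overlap and gene list steps were tested on simulated data. For peaks like limb SMARCA4 over neural tube, planted shares of 0, 5, 30 and 80% gave 2.49, 7.88, 32.0 and 80.6%. All 2717 simulated gene points were right. Among simulated gene lists for SMARCA4 heart, 95% of those with doubled peaks and 3.5% of unchanged ones reached the upper percentile. For the short midbrain list these shares were 35% and 1.5%, so a doubling there is often missed. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.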

Results

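The series mapped tagged coactivators in mouse embryos of day 11.5 and in ESC. SMARCA4 was mapped in face, forebrain, midbrain, hindbrain, neural tube, limb, heart and ESC. EP300 was mapped in face and ESC, SMARCC2 in face and hindbrain, and NCOA1 and NCOA2 in hindbrain. H3K4me1 (enhancers and the flanks of gene starts), H3K4me3 (active gene starts) and H3K27me3 (Polycomb) were mapped in limb and forebrain, and H3K27ac (active elements) in limb. Positions are in mm9.

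SMARCA4 occupied 35099 peaks in face, 14362 in neural tube, 13755 in heart, 7349 in forebrain, 6764 in ESC, 5460 in hindbrain, 5251 in limb and 1513 in midbrain. EP300 had 3589 peaks in face and 10356 in ESC, SMARCC2 11321 in face and 2272 in hindbrain, NCOA2 3444 and NCOA1 1414. The median count of tags per peak ranged from 7 in EP300 ESC and 8 in SMARCC2 hindbrain to 87 in SMARCC2 face and 91 in EP300 face. It was 37 in SMARCA4 heart, 31 in SMARCA4 midbrain, 36 in NCOA2 and 16 in NCOA1. Numbers of peaks in lists called in different ways do not rank the tissues. By the authors, every SMARCA4 midbrain peak had a false discovery rate of at least 50%, and so had 52.3% of EP300 face peaks. A rate of 5% or less was reached by 0% of SMARCA4 midbrain and NCOA1 peaks, 22.01% of EP300 face and 65.8% of NCOA2 peaks.

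How close the factors lay to gene starts differed widely. Within 1 kb of a start lay 89.0% of NCOA2 peaks (95% interval 87.9 to 90.0%), 76.1% of EP300 face peaks and 72.4% of SMARCA4 limb peaks. In SMARCA4 face it was 31.8%, in SMARCC2 face 32.0%, in SMARCA4 heart 21.8%, in SMARCA4 midbrain 19% and in SMARCA4 ESC 14.2%. SMARCC2 hindbrain had the lowest share, 3.52% (2.80 to 4.36%).

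**Figure D1:**
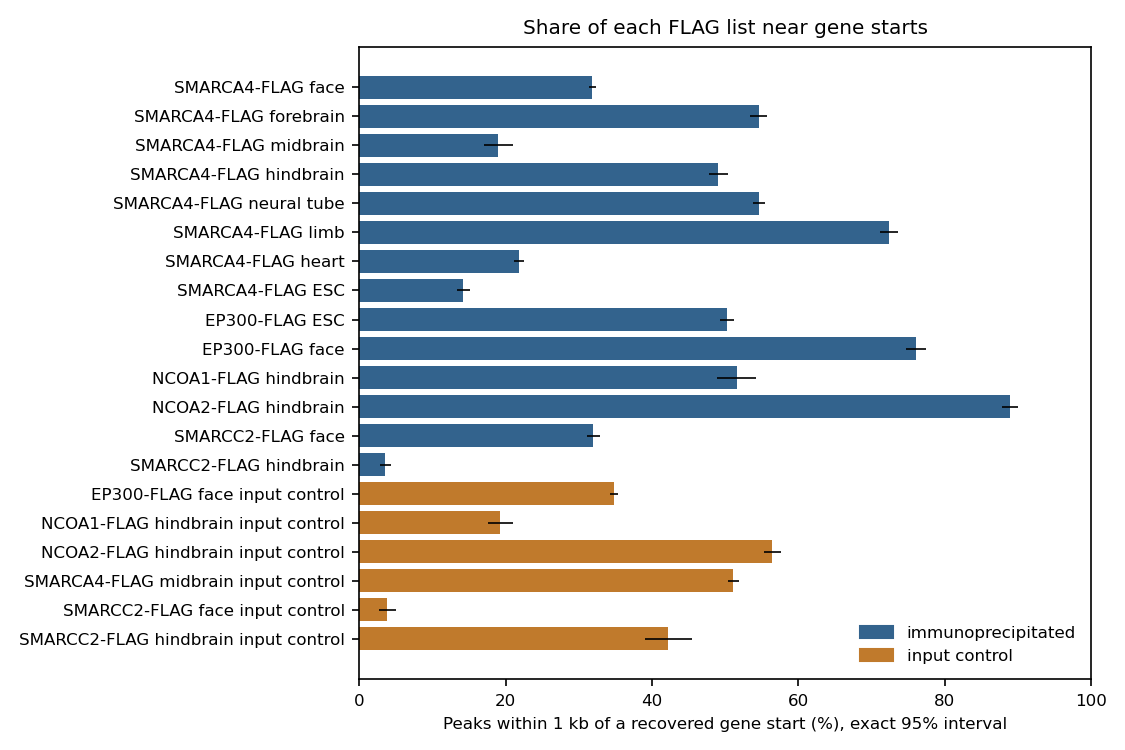
Share of peaks within 1 kb of a gene start in percent, for each FLAG list and each control list, with exact 95% intervals. NCOA2 stood at 89.0% and its control at 56.4%, while SMARCC2 hindbrain stood at 3.52% and its control at 42.2%.

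The first comparison set 6 FLAG lists against the lists of their own controls, which checks the labels. EP300 face shared most with its control: 2313 of 3589 peaks, or 64.4% (62.9 to 66.0%), against 1.82% after shifts. NCOA2 shared 25.3% and SMARCA4 midbrain 11.4%. NCOA1 shared 0.354% (5 of 1414) and SMARCC2 face 0.177% (20 of 11321). Of the SMARCC2 hindbrain peaks, 0 of 2272 lay over the control, which allows a share of up to 0.162%. Some controls had long lists: the EP300 face control had 28895 peaks and the midbrain control 19772, 13.1 times the 1513 peaks of the midbrain immunoprecipitation. Of the midbrain control peaks, 51.1% lay near a gene start, against 19% of the SMARCA4 midbrain peaks. At equal list lengths the shares over the control were 21.9% for EP300 face, 13.8% for NCOA2, 0.264% for SMARCA4 midbrain and 0.278% for SMARCC2 face.

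The next comparison asked which SMARCA4 regions the tissues shared. Merging the 8 lists gave 52768 regions, of which 36169 (68.5%) were found in 1 tissue. Of these 16.3% (15.9 to 16.7%) lay over H3K4me3 of limb or forebrain. The share over H3K4me3 was 60.4% for regions of 2 tissues and 94.2% for regions of 4. The 9 regions found in all 8 tissues all lay over H3K4me3. Of these 44.4% lay within 1 kb of a gene start. The nearest genes were Igfbp2, which codes for a carrier of insulin-like growth factors, Slc38a1, a neutral amino acid transporter, and Itpr1, the calcium channel of the endoplasmic reticulum. Itpr1 was 40047 bp away. The others were Caprin1, Ypel4, mKIAA1382, BC023818, Nanos3 and, at 30.8 kb, Ccr4.

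At the lengths given, the lists with the highest share of SMARCA4 peaks of their own were ESC, face and heart. In ESC, 68.3% (67.1 to 69.4%) of SMARCA4 peaks were found in no other tissue, in face 54.3% and in heart 52.8%. In hindbrain it was 24.1%, in neural tube 22.3%, in midbrain 19.2%, in forebrain 4.80% and in limb 1.66% (1.33 to 2.04%). Limb peaks lay over neural tube in 90.8% (90.0 to 91.6%), against 3.04% after shifts, and over face in 91.5%. Forebrain peaks lay over face in 90.6%, heart peaks in 36.2% and ESC peaks in 19.1%. Relative to shifts, midbrain and hindbrain were closest to each other, with 19.4% of midbrain peaks over hindbrain, 65.7 times the shifted share. By this measure, however, every other list was also closest to midbrain or hindbrain, so it does not single out the pair. Of merged regions the pair shared 4.36%, against 32.1% for limb with neural tube. Away from H3K4me3 the pair closest relative to shifts changed: forebrain over limb was 107.9 times and neural tube over limb 92.4 times, against 72.7 times for midbrain over hindbrain.

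The peaks of forebrain, neural tube and limb are wide, with medians of 3100, 2250 and 2300 bp against 489 bp in face and 158 bp in ESC, which raises any overlap. Shares of own peaks changed with list length: at equal lengths they were 33.7% in forebrain, 29.1% in limb, 66.3% in midbrain, 55.4% in hindbrain, 32.3% in face, 69.2% in heart and 90.4% in ESC, so that face fell below midbrain, hindbrain and forebrain. Without the face list they were 18.3% in forebrain, 4.72% in limb, 37.7% in midbrain and 38.0% in neural tube, while limb without neural tube had 5.18%. Pairs moved too: at equal lengths limb over neural tube was 47.5%, forebrain over face 35.8%, heart over face 15.1%, ESC over face 1.85% and SMARCA4-FLAG midbrain over SMARCA4-FLAG hindbrain 10.05%, and away from H3K4me3 70.3% of 522 limb peaks lay over neural tube and 38.3% over face, with 56.0% of forebrain, 13.8% of heart and 7.01% of ESC peaks over face and 5.29% of midbrain peaks over hindbrain.

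**Figure D2:**
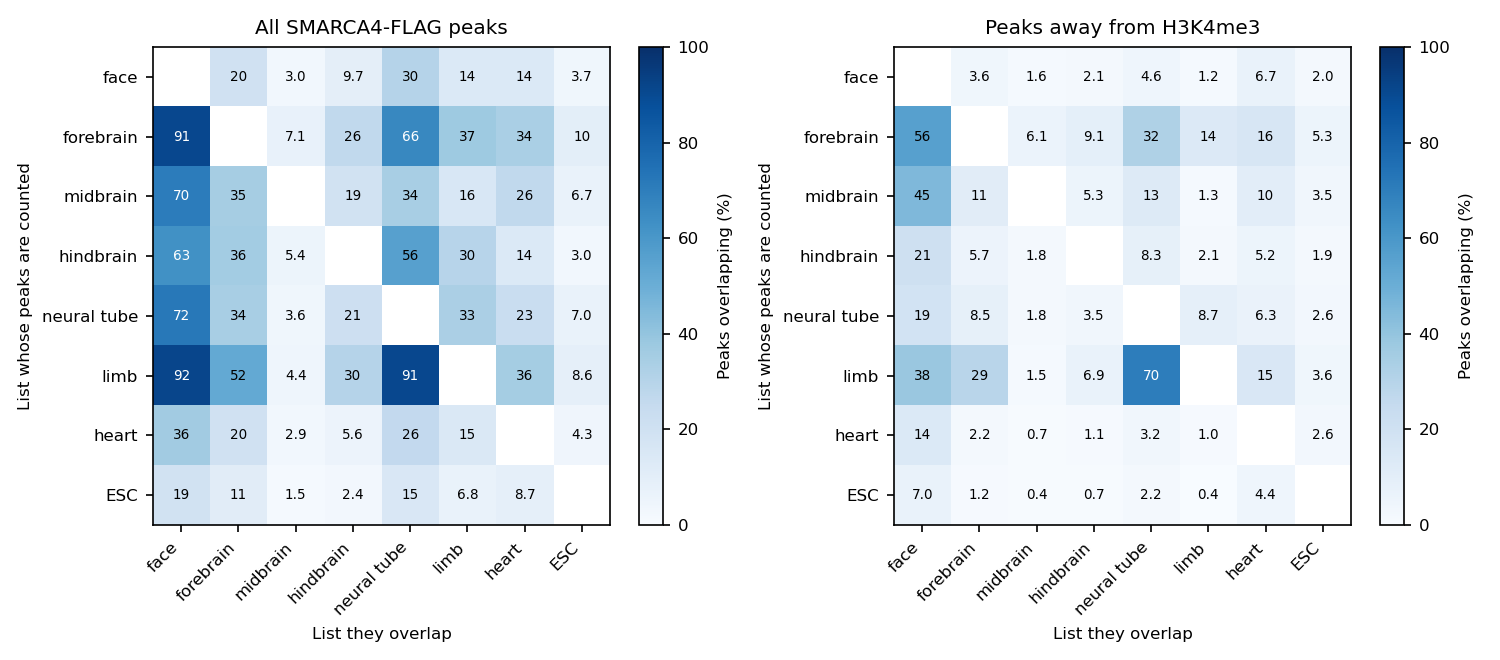
Share of the SMARCA4 peaks of each tissue that overlapped the SMARCA4 peaks of every other tissue, in percent, for all peaks (left) and for peaks away from H3K4me3 (right). Limb peaks reached 90.8% over neural tube (70.3% away from H3K4me3) and 91.5% over face, while ESC peaks reached 19.1% over face and 8.71% over heart.

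In 6 of 8 tissues SMARCA4 peaks were called more frequent at genes known for the identity of the tissue than at random lists. ESC genes of pluripotency held 2.74 times as many ESC peaks as matched random lists (percentile 100), with peaks at 22 of 23 placed genes. Nanog, a core pluripotency factor, had 9 ESC peaks within 100 kb, and Klf2, a factor of naive pluripotency, and Mycn, a MYC family gene, had 5 each. Heart genes held 2.52 times as many heart peaks (percentile 100), with peaks at 21 of 21 genes. Gata4, a cardiac transcription factor, had 21 heart peaks and 0 to 5 in each other tissue. Myl7, the atrial myosin light chain, and Tbx20, a cardiac T-box factor, had 9 each. Hand2, which acts in heart and limb, had 8 heart peaks and 1 limb peak, and Tbx5, of heart and forelimb, had 8 and 0.

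Face genes held 1.44 times as many face peaks (percentile 100), at 22 of 22 genes. The homeobox genes Prrx2, Alx4 and Barx1, which act in craniofacial mesenchyme, had 18, 13 and 12. Neural tube genes held 1.40 times as many neural tube peaks (percentile 99.9), with 9 at Pax2 and 7 each at Hoxd8 and Lbx1, which mark spinal interneurons or trunk position. Forebrain genes held 1.61 times as many forebrain peaks (percentile 99.8), at 13 of 16 genes, with 3 each at Lhx2, a selector of cortex, and Neurog2, a proneural factor, and 2 at Dlx1 of the ventral forebrain. Midbrain genes held 2.22 times as many midbrain peaks (percentile 97.7), at 8 of 15 genes: 2 at Otx2, which sets up forebrain and midbrain, and 1 each at En2 and Gata3. The midbrain list also held 2.71 times as many peaks at forebrain genes, short of a call (percentile 96.9).

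The remaining 2 tissues were not called at their own genes. Limb genes held 1.30 times as many limb peaks (percentile 95.3), with 4 each at Hoxd12 and Lmx1b, a dorsal selector, and 3 at Hoxa10. Hindbrain genes held 0.780 times as many hindbrain peaks (percentile 20.6), with 1 each at Egr2, a rhombomere gene, and Gbx2.

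SMARCA4 was also called low at genes of other tissues. The limb list held 0.348 times as many peaks at forebrain genes (percentile 0.135), 0.426 times at midbrain genes (0.07) and 0.5 times at heart genes (0.04). At midbrain genes the NCOA2 control was called low too, at 0.442 times (0.115). The hindbrain list, whose tissue tag says forebrain, held 0.280 times as many at forebrain genes (0.165), and the heart list 0.402, 0.236 and 0.487 times at forebrain, hindbrain and neural tube genes. Forebrain was low at hindbrain (0.574) and limb genes (0.640), ESC at limb genes (0.497), and face (0.853) and neural tube (0.780) at heart genes. Lost were limb at forebrain genes in 50 kb territories (percentile 6.01), and by nearest gene limb at midbrain (5.85), heart at neural tube (4.33) and forebrain at hindbrain (16.4) and limb genes (87.4). Without peaks within 1 kb of starts limb at midbrain (22.9) and forebrain at limb genes (7.87) were lost, and with exact gene points alone forebrain at hindbrain genes (6.49).

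The face list, the longest, held more peaks than the tissue's own list at many of these genes: 11 at Myl7, 6 each at Mycn and Klf2, 10 at Pax2, 11 at Lbx1, 8 each at Lhx2 and Otx2, 7 each at Neurog2 and Dlx1, and 5 each at En2 and Gata3. It also held 14 at Lmx1b, 7 each at Hoxd12 and Hoxa10, 10 at Gbx2 and 6 at Egr2.

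Control lists were called high at 3 of these gene lists. Neural tube genes held 1.65 times as many peaks of the midbrain control (percentile 100) and 1.32 times as many of the EP300 face control (99.7) and 3.03 times as many of the SMARCC2 hindbrain control (99.4). Hindbrain genes held 4.87 times as many peaks of the SMARCC2 face control (percentile 100), and face genes 1.24 times as many of the EP300 face control (99.2, at 22 of 22 genes). An excess at neural tube and face genes was thus also present in controls, and no control list of the SMARCA4 neural tube and face libraries themselves was used here. None of the 6 controls was called high at forebrain, midbrain, limb, heart or ESC genes.

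The forebrain call was lost when peaks within 1 kb of starts were left out (percentile 77.8), and the midbrain call was lost then (85.7), in 50 kb territories (94.6) and with peaks given to the nearest gene (92.0). Given to the nearest gene, face fell to 95.9 and neural tube to 97.3, also short of a call.

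**Figure D3:**
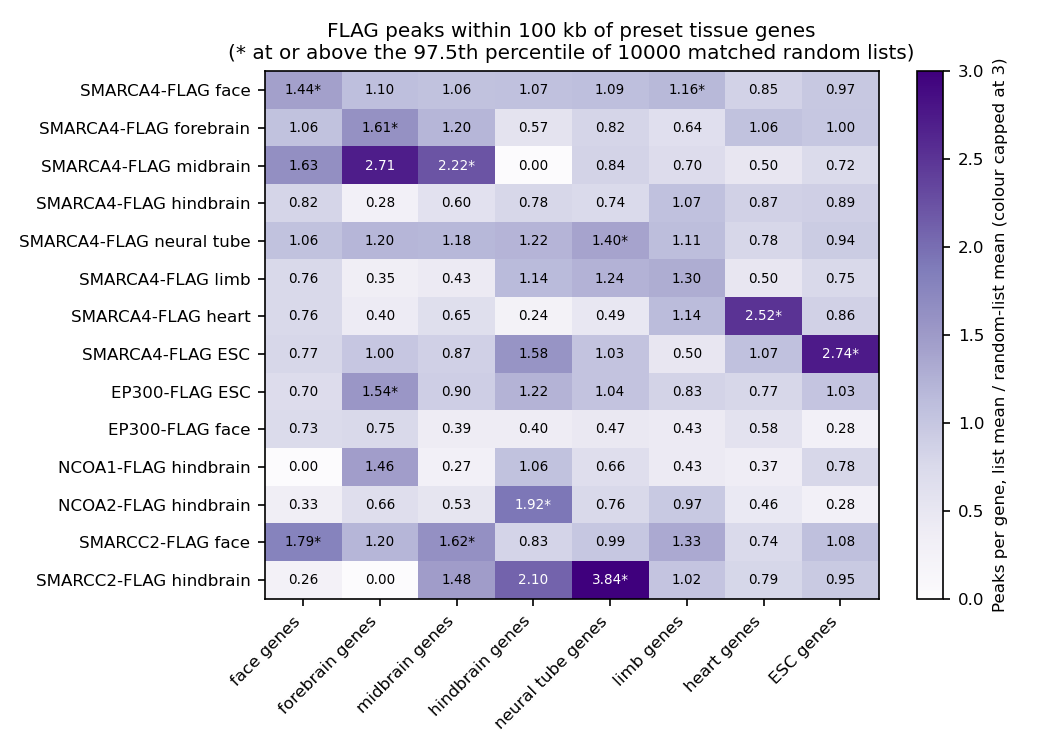
Mean number of peaks per gene of each preset gene list relative to matched random lists, for each FLAG list, with an asterisk where a list was called high. ESC and heart genes stood at 2.74 and 2.52 times the random mean in their own tissues, and hindbrain genes at 0.780.

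Endothelial genes, of a cell type present in the embryonic tissues but not in ESC, were called high in no SMARCA4 list: face held 1.16 times the random mean (percentile 96.4), heart 1.19 times (78.7) and midbrain 1.38 times (76.6), while ESC was called low at 0.489 times (2.07). SMARCC2 hindbrain was called high at 2.83 times (percentile 98.6). The ESC call was lost in 50 kb territories (25.2) and by nearest gene (4.75), and so was that of SMARCC2 hindbrain (51.0 and 71.8). Eng, a receptor of endothelial cells chosen after its values were seen, had 20 face peaks and 7 heart peaks. Housekeeping genes held 1.46 times as many SMARCA4 heart peaks (percentile 98.4) and 3.32 times as many NCOA1 peaks (percentile 100). SWI/SNF subunits and tagged factors held 1.86 times as many NCOA1 peaks (percentile 97.8) and 0.984 times as many SMARCA4 face peaks (percentile 39.9). With 7 of 12 erythroid genes placed, that check is void. The housekeeping call in heart was lost in 50 kb territories (percentile 93.6), by nearest gene (88.0) and without peaks within 1 kb of starts (83.4), and so was that of SWI/SNF subunits in NCOA1 without such peaks (89.8).

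The peaks of highest rank found in 1 tissue alone often lay far from a gene start. In midbrain one lay 26.7 kb from En2, a midbrain and hindbrain patterning gene, on chromosome 5 at 28518714 to 28519306, with 25 tags. In limb they lay 178 kb from Osr1 (chromosome 12, 9758001 to 9760500), a regulator of limb connective tissue, 30.6 kb from Dnm3os and 34.5 kb from Trak1. In neural tube they lay 42.5 kb from Nhlh2, a neuronal basic helix-loop-helix factor, 81.8 kb from meis2a and 33.3 kb from Gse1. Heart had them 31.0 kb from Sgms1 (chromosome 19, 32253548 to 32256903), with 297 tags, at Akap6, an anchor of protein kinase A in heart muscle, and 108 kb from Etv6. In ESC the nearest genes were Grm2, Lypd5 and Kirrel, in face Mogat1, Spsb1 and AU022252, in forebrain Pxmp3, Tbrg1 and Cstb, in hindbrain AK050283, Svep1 and AK076805, and in midbrain also AK017104 and Ak1. The peak at Mogat1 lay in 3 input or control lists and that by Spsb1 in 1, and the others named here in 0.

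Co-occupancy asked whether coactivators lay together within a tissue. In face, 72.4% (71.5 to 73.2%) of SMARCC2 peaks and 77.8% (76.4 to 79.1%) of EP300 peaks lay over SMARCA4, against 3.78% and 2.72% after shifts. SMARCC2 is a subunit of the same complex as SMARCA4. Relative to shifts, however, SMARCC2 face stood at 19.2 times over SMARCA4 and EP300 face at 28.6 times, with a lower ceiling for SMARCC2. Away from H3K4me3 43.9% of SMARCC2 face peaks lay over SMARCA4, against 11.3% of EP300 peaks. SMARCC2 face peaks are wider, with a median of 1590 bp against 1078 bp, and the cause of the contrast was not tested. In face, EP300 peaks lay over SMARCC2 in 21.0%. In hindbrain, 41.9% (39.3 to 44.5%) of NCOA1 peaks lay over NCOA2, a paralogue, and 30.1% of NCOA2 peaks lay over SMARCA4. SMARCC2 hindbrain peaks lay over SMARCA4 hindbrain in 1.5% (1.04 to 2.08%). In ESC, SMARCA4 peaks lay over EP300 in 3.03% (2.64 to 3.47%), while EP300 face peaks lay over EP300 ESC in 45.9%. As raw shares over lists of different length, overlaps across tissues were often larger than those within a tissue. NCOA1 hindbrain peaks lay over EP300 face in 43.5%. NCOA2 hindbrain peaks lay over SMARCA4 face in 89.4% and over SMARCA4 neural tube in 84.1%. EP300 ESC peaks lay over SMARCA4 face in 51.9%, over SMARCA4 neural tube in 43.2% and over SMARCA4 ESC in 1.98%. Relative to shifts the order turned for NCOA2, at 91.1 times over SMARCA4 hindbrain against 34.9 over face and 39.4 over neural tube. The shifted shares were 0.331% over hindbrain, 2.56% over face and 2.14% over neural tube. The larger ones cap the folds over face and neural tube far lower, so the turned order shows no preference for the same tissue. NCOA1 stood at 228.6 times over EP300 face and 220.9 over NCOA2. EP300 ESC kept the order, at 40.4, 26.7 and 16.9 times over SMARCA4 face, neural tube and ESC.

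At equal lengths, or without peaks of control lists, EP300 over SMARCA4 in face was 17.3% or 22.5%, SMARCC2 over SMARCA4 34.8% or 49.9%, NCOA1 over NCOA2 29.9% or 2.22%, NCOA2-FLAG hindbrain over SMARCA4-FLAG hindbrain 17.0% or 6.67%, EP300-FLAG face over SMARCC2-FLAG face 6.32% or 6.08%, SMARCC2 over SMARCA4 in hindbrain 0.424% or 0.368%, SMARCA4 over EP300 in ESC 2.45% or 1.18%, and EP300 face over ESC 25.5% or 10.3%. Among regions bound in any FLAG list, the odds ratio was 0.544 for the ESC pair and 0.263 for SMARCC2 with SMARCA4 in hindbrain. That background leaves out regions bound in no list, which lowers the ratio for lists with many peaks of their own. The ratios therefore do not overturn the excess over shifts, 17.2 times for SMARCA4 over EP300 in ESC and 11.3 times for SMARCC2 over SMARCA4 in hindbrain.

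The other factors were set against the same gene lists, each from 1 library in 1 tissue. SMARCC2 face held 1.79 times as many peaks at face genes (percentile 100) and 1.62 times at midbrain genes (percentile 99.6), with 10 at Prrx2, 8 at Alx4 and 11 at Lmx1b. EP300 ESC held 1.03 times as many at ESC genes (percentile 59.8) and 1.54 times at forebrain genes (percentile 99.9). NCOA2 held 1.92 times as many at hindbrain genes (percentile 99.9), with 3 at each of Hoxa2 and Hoxa3, which share territories. SMARCC2 hindbrain held 3.84 times as many at neural tube genes (percentile 100), with 2 at Hoxc6 and Hoxc8 and 3 at Hoxc9, again neighbours, but its control held 3.03 times as many there (percentile 99.4). By nearest gene the calls were lost for NCOA2 (percentile 79.7), SMARCC2 hindbrain (69.4) and SMARCC2 face at face genes (86.3) and midbrain genes (83.4), while EP300 ESC reached 98.7 at ESC genes. In 50 kb territories SMARCC2 face at midbrain genes fell to 89.3 and EP300 ESC at forebrain genes to 95.4, and SMARCC2 face at midbrain genes also lost its call without peaks within 1 kb of starts (85.5).

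EP300 face was not called at its own face genes, at 0.727 times (percentile 11.8), and was called low at midbrain (0.390), hindbrain (0.395), neural tube (0.466), limb (0.426), heart (0.581) and ESC genes (0.279). NCOA2 was low at midbrain (0.530), face (0.335), heart (0.457) and ESC genes (0.278), EP300 ESC at face genes (0.696), and NCOA1 had 0 peaks at face genes. The NCOA2 control was itself called low at midbrain genes, at 0.442 times (percentile 0.115). For the factors too, matching on the total over all FLAG lists lowers values at genes where another FLAG list is high. Without peaks within 1 kb of starts each of these low calls of the factors was lost, at percentiles of 4.3 to 79.9. By nearest gene those of EP300 face were lost except at ESC genes (4.21 to 36.9), and so were those of EP300 ESC (10.5) and of NCOA2 at midbrain genes (40.6). Lost were in 50 kb territories those of EP300 face at limb (2.58) and neural tube genes (24.6) and of NCOA2 at midbrain genes (9.92), and with exact gene points alone those of EP300 face at neural tube genes (2.68) and of NCOA2 at midbrain genes (2.51).

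The top peaks were named for each factor. For NCOA2 they lay at Pgk1, a glycolytic enzyme gene (X chromosome, 103381692 to 103382874, 274 tags), 15.6 kb from Taf9b, and 4.25 kb from 1810026J23Rik, the last 8154 bp wide with 1916 tags. For NCOA1 they lay at Senp6 and Kcmf1 and 24.6 kb from Kiaa0240. For EP300 a region 228 kb from AK017048 led the ESC list and was among the top 3 in face, beside Olfr1344 and AK161589, with Scrt1 and Erich1 the next in ESC. For SMARCC2 face they were broad, 14137 bp at 2.12 kb from Shb, and 13978 and 12353 bp at 16.8 kb from Igsf3 and 35.7 kb from Ahdc1. For SMARCC2 hindbrain, at 47.6 kb from Bnc2, 90.7 kb from Mc3r and 792 kb from Rgs18, they held 12 to 17 tags. Many of these top peaks also lay in input or control lists: 1810026J23Rik in 3 of them and in 0 other FLAG lists, Senp6 in 3, Kiaa0240 and Shb in 2, and Kcmf1, Scrt1, Erich1, Igsf3 and Ahdc1 in 1.

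SMARCA4 peaks were then set against histone marks of the same tissue. In limb, 89.3% (88.4 to 90.1%) lay over H3K4me3, 85.9% over H3K4me1, 68.4% over H3K27ac and 37.9% (36.6 to 39.2%) over H3K27me3, against 3.72, 10.9, 2.85 and 3.20% after shifts. Controls were enriched over these marks too: the NCOA2 control lay over limb H3K4me3 in 64.5% and H3K27me3 in 24.3%, 34.9 and 11.98 times the shifted shares, and the midbrain control in 59.8% and 26.3%, 26.96 and 11.4 times, against 23.98 and 11.8 times for SMARCA4 limb. In forebrain 79.1% lay over H3K4me3, 84.6% over H3K4me1 and 26.8% over H3K27me3. Few SMARCA4 peaks had none of the marks: 3.68% in limb and 4.52% in forebrain. Limb peaks with H3K4me3 and H3K27me3 together made up 35.7%, and forebrain peaks 23.8%. The top limb peaks with H3K27me3 lay at Hoxd9, a Hox gene of trunk and limb, Nfatc2, Cd24a, Whrn and Rragd, and the forebrain ones at Cnn3, Samd4, 1500001A10Rik, mKIAA1382 and 24.7 kb from AK021191. Each of these 10 peaks lay in 1 to 3 input or control lists.

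Seen from gene starts, H3K4me3 regions that also carried H3K27me3 held SMARCA4 more often. In limb it was 28.1% (27.03 to 29.2%) against 21.5% (20.8 to 22.2%) of those without, and in forebrain 41.5% (39.9 to 43.0%) against 33.1% (32.2 to 33.9%). The direction was the same in each of 4 groups of regions by width in both tissues, with overlapping intervals in the widest group of both and in the narrowest of forebrain. H3K4me1 found in 1 tissue alone made up 9541 regions in forebrain and 33535 in limb. Away from H3K4me3, 13.6% of midbrain SMARCA4 peaks lay over the forebrain ones and 9.42% over the limb ones, 16.3 and 3.09 times the shifted shares. These shares were 11.7% and 12.3% for forebrain, 8.11% and 10.9% for hindbrain, 7.998% and 13.1% for neural tube, 8.24% and 20.1% for limb, 4.33% and 29.4% for face, 4.47% and 20.3% for heart, and 5.60% and 10.2% for ESC. Relative to shifts, forebrain regions stood above limb ones in 6 of 8 lists, with 11.8 and 4.48 times in hindbrain, 8.45 and 4.34 in ESC, 6.16 and 1.91 in forebrain, 5.89 and 2.76 in neural tube and 5.48 and 4.06 in limb, but 5.81 and 11.1 in face and 5.88 and 7.55 in heart. With a peak midpoint required inside the region, the forebrain share over H3K27me3 was 6.31%. Without peaks of control lists the limb shares were 41.4% for H3K4me3, 39.3% for H3K27ac and 18.7% for H3K27me3, and the forebrain ones 39.0% for H3K4me3 and 13.9% for H3K27me3; away from H3K4me3 of the tissue, limb H3K4me1 was 55.5%, H3K27ac 22.3% and H3K27me3 20.7%, and forebrain H3K27me3 14.3%.

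**Figure D4:**
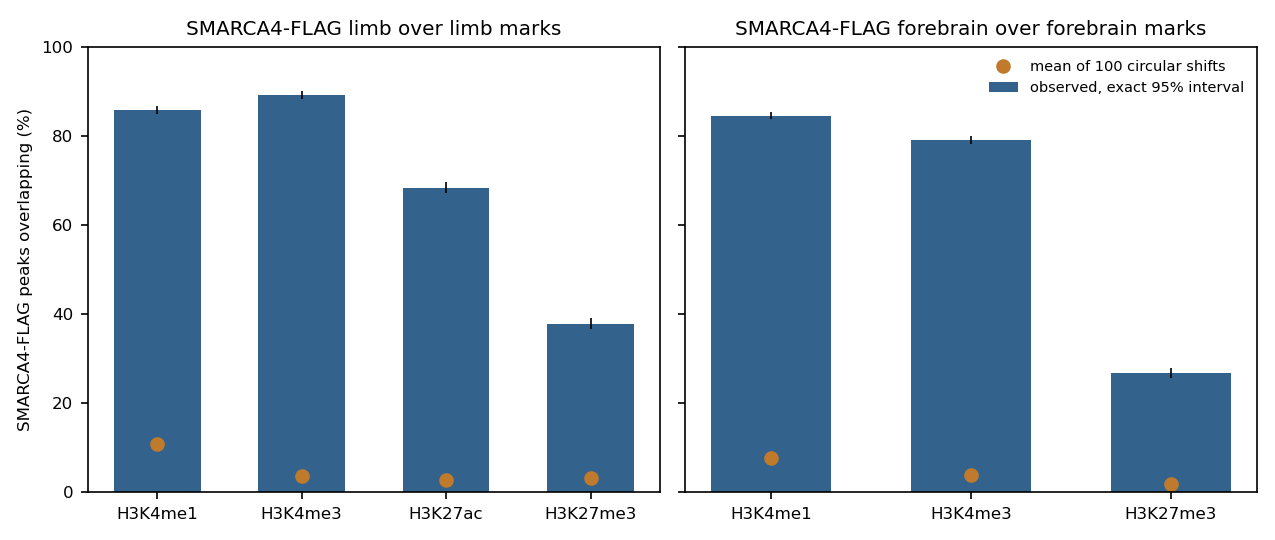
Share of SMARCA4 peaks over each histone mark of the same tissue in percent, with exact 95% intervals, and the mean after circular shifts. In limb 89.3% lay over H3K4me3 and 37.9% over H3K27me3, and in forebrain 79.1% and 26.8%.

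The last comparison set limb and forebrain marks side by side. Of forebrain regions, 93.1% (92.7 to 93.5%) of H3K4me3 lay over the same mark in limb, 72.6% of H3K4me1 and 54.6% (53.7 to 55.5%) of H3K27me3. Of limb regions, which are more numerous, 78.6%, 42.4% and 36.1% lay over forebrain. Relative to shifts, forebrain over limb was 26.1 times for H3K4me3, 20.1 times for H3K27me3 and 7.68 times for H3K4me1. H3K27me3 covered 33.8% of H3K4me3 regions in limb and 24.0% in forebrain, and 10.5% of limb H3K27ac regions. With an overlap of 50% of the shorter region the forebrain share was 13.5%. Forebrain H3K27me3 lay at neural tube genes 5.66 times as often as at random lists (percentile 100), and limb H3K27ac at limb genes 1.34 times (percentile 99.5) and at midbrain genes 0.449 times (percentile 0).

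Regions of 1 tissue alone named a few developmental genes. A forebrain H3K4me3 region of 10310 bp lay 1.14 kb from Nr2e1, a regulator of neural stem cells, and others had Aurkb and Axin1 as nearest genes. Forebrain H3K4me1 lay 24.4 kb from Nova2, a neuronal splicing factor, and otherwise Dnahc2 and Eml1 were nearest. For limb H3K4me3 the nearest genes were Fscn1, Ccdc142 and Otos, and for limb H3K4me1 Gpr146, Selplg and Nthl1. For H3K27me3 of forebrain they were AK007148, AK133929 and 1700011F03Rik, and of limb C530008M17Rik, Myo15b and 1600002O04Rik. Of the regions named here, that of C530008M17Rik lay in 3 input or control lists, those of Gpr146, Nr2e1 and Myo15b in 2 and that of Otos in 1. Of the histone regions, at most 0.563% lay over their own input.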

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

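The tests for swapped labels and for open chromatin were chosen after the result was seen. SMARCC2, a subunit of the SWI/SNF complex, stood on opposite sides of its controls in face and hindbrain, which drew attention to it. The share of peaks near gene starts, immunoprecipitation minus control, was 28.2 percentage points in face and -38.7 in hindbrain. The difference was not tested, since each tissue had 1 library.

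SMARCC2 hindbrain peaks hardly met other lists and lay away from gene starts (3.52%), like the SMARCC2 face control (3.71%) and unlike their own (42.2%). A swap of the 2 labels cannot be told apart from the labels as given, since the values go both ways away from H3K4me3. The control peaks lay over SMARCC2 face in 2.51% (1.30 to 4.34%), 7.10 times the shifted share, against 0.692% (0.388 to 1.14%) of the immunoprecipitated peaks, which goes with a swap, but over the other controls in 13.6% (10.6 to 17.0%) against 1.29% (0.859 to 1.86%), which goes against it. Whether thin pileups account for the list could not be settled. The top 10% of peaks by score lay over SMARCA4 hindbrain, SMARCA4 face or SMARCC2 face in 1.32% (0.273 to 3.81%). Of the other peaks 5.48% did, and of all peaks 1.83% after shifts. That the top peaks shared no more goes with thin pileups. The median of 8 tags per peak does not decide. EP300 ESC had 7 and lay over SMARCA4 face in 51.9%, but the NCOA2 control also had 7, with 65.8% over H3K4me3. Sharing with another list at such counts thus does not show that peaks were bound. The authors' false discovery rate, at most 5% for 100% of SMARCC2 hindbrain peaks, goes against thin pileups. Hindbrain and face differ as tissues, which stays open and untested.

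The SMARCA4 midbrain control had 19772 peaks against 1513 and lay nearer to gene starts. A swap could not be settled. At equal lengths and away from H3K4me3, 36.9% (33.0 to 40.8%) of control peaks lay over the other SMARCA4 lists, against 56.7% (52.6 to 60.7%) of the immunoprecipitated peaks. That goes against a swap. The authors' false discovery rate of the SMARCA4 midbrain peaks, with a median of 100%, does not favour the labels as given. Whether open chromatin entering unenriched input accounts for the long list could not be decided. Away from H3K4me3 the control lay over the other control lists in 30.9%, 51.5 times the shifted share. It lay over the immunoprecipitated lists in 24.4%, 11.9 times. The shifted share is larger over the immunoprecipitated lists, which caps the fold they can reach below that of the controls. No measure of open chromatin was used. No biological explanation was tested, as both libraries come from midbrain.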

How the results depend on the processing

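Limits on the authors' false discovery rate, exact gene points alone, and leaving out midbrain and hindbrain together were chosen after the result was seen. In all, 1078 alternative values were computed for 273 results. Of these values 727 stayed the same, 51 lost a call, 38 gained one and 12 reversed. A further 250 moved beyond their interval or, for counts, by over 1.5 times. Gene list values called neither time count as the same. Those that crossed the middle of the percentiles with a call on 1 side only count as reversed, so lost and gained calls are undercounted. Some outcomes were fixed by the setting or nearly so: keeping the higher-scoring part of each list moved 31 values. Merging touching peaks left 32 values the same, and so did keeping chromosomes 1 to 19, X and Y. The tally is therefore no measure of robustness. For the 44 results that answer a comparison, 56 of 153 values stayed the same, 90 moved, 6 lost a call and 1 reversed. Of the calls at a tissue's own genes, heart and ESC held under every alternative run. At an authors' false discovery rate of 5% or less, 0% of SMARCA4 midbrain and NCOA1 peaks, 22.01% of EP300 face and 65.8% of NCOA2 peaks remained, and over 99% in the SMARCA4 heart and both SMARCC2 lists. No depth per library was known, so list lengths limit every overlap, and the cause of the changes below was not tested. No paired analysis was possible because no condition has more than 1 library.

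The number of peaks per list, all lists together, was 177374 with the higher-scoring part of each list, of 354733. At equal list lengths, peaks over their own control were 21.9% in EP300 face, 13.8% in NCOA2, 0.264% in SMARCA4 midbrain and 0.278% in SMARCC2 face. SMARCA4 peaks of 1 tissue, over all lists 40.4%, were 41.9% with an overlap of 50% of the shorter peak, 48.9% with midpoints within 500 bp, 51.1% at equal lengths, 71.9% without peaks of control lists, 78.1% without peaks over H3K4me3, 38.9 to 48.9% with each tissue left out, and 43.0% without midbrain and hindbrain. SMARCA4-FLAG regions in 5 or more tissues, 2573 in all, numbered 148 at equal lengths, 200 without peaks of control lists, 72 without peaks over H3K4me3, 886 to 2382 with each tissue left out (886 without face, 942 without neural tube, 2382 without midbrain), and 1459 without midbrain and hindbrain. SMARCA4-FLAG limb over SMARCA4-FLAG neural tube was 73.5% by midpoints, 47.5% at equal lengths, 68.7% without peaks of control lists and 70.3% without H3K4me3, and forebrain over face was 58.9, 35.8, 68.7 and 56.0%.

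With an overlap of 50% of the shorter peak, EP300 face over SMARCA4 was 76.1%, NCOA2-FLAG hindbrain over SMARCA4-FLAG hindbrain 28.3%, SMARCA4-FLAG ESC over EP300-FLAG ESC 2.5% and SMARCC2 face over SMARCA4 69.3%. At equal lengths EP300 face over EP300 ESC was 25.5%, EP300 face over SMARCA4 17.3%, NCOA1 over NCOA2 29.9%, NCOA2 over SMARCA4 17.0%, SMARCA4 ESC over EP300 2.45% and SMARCC2 face over SMARCA4 34.8%. Without peaks of control lists these were 10.3, 22.5, 2.22, 6.67, 1.18 and 49.9%. Counted as reversed were odds ratios over the union of FLAG regions for SMARCA4 and EP300 in ESC (0.544). So were those for SMARCC2 hindbrain with SMARCA4 (0.263), NCOA1 (0.371), NCOA2 (0.325) and SMARCC2 face (0.151). That union leaves out regions bound in no list, so these ratios do not overturn the excess over shifts.

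For SMARCA4-FLAG limb over H3K4me1 limb, SMARCA4-FLAG limb over H3K4me3 limb, SMARCA4-FLAG limb over H3K27ac limb and SMARCA4-FLAG limb over H3K27me3 limb, a midpoint inside the region gave 71.5, 87.1, 63.7 and 30.5%, the higher-scoring histone regions 69.8, 67.7, 57.0 and 31.3%, and peaks outside control lists 65.4, 41.4, 39.3 and 18.7%. The higher-scoring limb peaks gave 87.1, 91.4 and 72.4% for the first 3, and peaks away from H3K4me3 gave 55.5% for H3K4me1, 22.3% for H3K27ac and 20.7% for H3K27me3. For SMARCA4-FLAG forebrain over H3K4me1 forebrain, and then H3K4me3 and H3K27me3, midpoints gave 59.5, 71.3 and 6.31%, the higher-scoring histone regions 60.9, 44.3 and 19.6%, and peaks outside control lists 78.5, 39.0 and 13.9%. The higher-scoring forebrain peaks gave 87.5 and 85.4% for the first 2, and peaks away from H3K4me3 74.8% for H3K4me1 and 14.3% for H3K27me3. H3K4me1 forebrain over limb was 71.1% and the same share 51.7% for H3K27me3 with an overlap of 50%, and 59.3% for H3K4me1, 90.0% for H3K4me3 and 52.9% for H3K27me3 at equal numbers. H3K4me3 over H3K27me3 with an overlap of 50% was 32.1% in limb and 13.5% in forebrain.

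By nearest gene only, the percentile of face genes in SMARCA4 face was 95.9, of midbrain genes in midbrain 92.0 and of neural tube genes in neural tube 97.3. It crossed the middle of the percentiles, counted as reversed, to 98.3 for ESC genes in face, 87.4 for limb genes in forebrain, 0.670 for neural tube genes in limb and 1.89 for housekeeping genes in ESC. Of these, limb genes in forebrain lost a low call (from 0.605), and neural tube genes in limb gained one (from 86.7). In 50 kb territories midbrain was 94.6. Without peaks within 1 kb of a start, forebrain was 77.8 and midbrain 85.7, and values counted as reversed were 69.5 for hindbrain genes and 79.9 for heart genes in EP300 face and 97.7 for limb genes in NCOA2. Those of EP300 face were lost low calls, and that of NCOA2 was a gained high call.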

Other observations

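The tests of gene starts and of the calling grid were chosen after the result was seen, and so were the genes named here beyond the rule. Polycomb marked most of the tissue gene lists in both tissues, but heart genes were called in neither: they held 1.36 times as many forebrain H3K27me3 regions as random lists (percentile 91.1) and 1.44 times as many limb ones (96.6). Forebrain H3K27me3 held 4.64 times as many regions at hindbrain genes, 4.38 times at forebrain genes, 4.31 times at midbrain genes and 3.98 times at limb genes as random lists (each percentile 100), against 0.934 times at endothelial and 0.471 times at housekeeping genes. Limb H3K27me3 held 3.91 times as many at neural tube genes and 2.21 times at limb genes. H3K4me1 of limb held most at neural tube genes, 1.83 times as many regions as random lists, then 1.69 times at face, 1.58 times at hindbrain, 1.5 times at limb and 1.39 times at endothelial genes (percentile 99.5), and forebrain H3K4me1 held 1.89 times as many at forebrain genes.

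Some members of a tissue list had more SMARCA4 peaks in other lists. Meis1, which patterns the proximal limb, had 13 heart peaks, 10 face peaks and 0 limb peaks. Wnt1, of the dorsal midbrain and neural tube, had 9 neural tube peaks, 11 face peaks and 1 midbrain peak. Pax7, a midbrain list gene also of dorsal neural tube and neural crest, had 8 neural tube, 7 face and 1 midbrain peaks. Limb genes as a list held 1.16 times as many face peaks as random lists (percentile 99.1, and 89.2 in 50 kb territories).

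Regions away from H3K4me3 that recurred in lists of 3 or more of the 5 factors numbered 150, of which 48.0% (39.8 to 56.3%) were also in an input or control list, against 10.8% of regions of 1 factor, and 78.0% carried H3K4me1 of limb or forebrain, against 42.5%. The 38 regions with at least 2 of EP300, NCOA1 and NCOA2 carried H3K4me1 in 36.8%, and the 2702 other regions with SMARCA4 and SMARCC2 in 92.9%. Regions of all 5 factors lay 25.4 kb from Phf21b, 228 kb from AK017048 and 1.21 kb from Jund1. EP300 ESC peaks had a median of 7 tags and a 50.2% share near gene starts, and the NCOA2 control had a median of 7 and a 56.4% share.

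Limb SMARCA4 peaks lay mostly over neural tube peaks. Shared gene starts are argued against as the whole account, because away from H3K4me3 70.3% (66.2 to 74.2%) of limb peaks lay over neural tube, against 38.3% (34.1 to 42.6%) over the longer face list. The 50 bp grid that limb, neural tube and forebrain lists share is argued against as the whole account too, since at equal lengths and away from H3K4me3 49.6% lay over neural tube and 29.1% over forebrain; a part in it stays open, since relative to shifts limb stood closest to these 2 lists, at 83.4 and 97.4 times. Mixing of tissue or libraries could not be settled: H3K4me1 found in forebrain alone was carried by 7.90% (5.36 to 11.2%) of shared limb peaks and 9.03% of the others, which goes against mixing, while limb H3K4me1 was carried by 50.4% (45.2 to 55.6%) of shared limb peaks and 62.6% (54.5 to 70.2%) of the others, which goes the other way with overlapping intervals, and no neural tube mark was used here. Regions that limb and neural tube use in common may also account for it, a hypothesis that stays untested.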
